A study of Mus musculus with 6 samples.

How the data were processed

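Wild type C57Bl6/J mice were exposed to warm temperatures in 3 numbered warm challenges. Per the labels' protocols, brains were cut into 0.5 mm sections and the anterior hypothalamus was dissected, and the labels name the tissue as preoptic neurons. PhosphoTRAP is an immunoprecipitation of ribosomes with an antibody against phosphorylated ribosomal protein S6 (sites 244 and 247), a modification that follows neuronal activity. Each warm challenge gave 1 library of total RNA (the input) and 1 library of RNA bound to phosphorylated S6 (the immunoprecipitate, IP), which makes 6 libraries, 3 per group. Per the labels' protocols, cDNA was amplified with an Ovation kit before library preparation, and the libraries were sequenced on an Illumina instrument.

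The authors deposited 1 table of gene-level RPKM (read counts scaled to gene length and library size) on a linear scale, per the file headers, with 1 column per library and no pooling. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here. The table lists 13724 gene entries with 13712 distinct symbols, 12 of which stand on 2 entries that were kept apart. Every listed value lies above 0.1 RPKM, and the smallest is 0.101, so genes at or below 0.1 RPKM in any library are not listed. Genes that fell to this floor in 1 fraction are therefore missed by every comparison. A gene name table matched 12033 symbols, and RefSeq symbols or synonyms (assembly GRCm38, used for names only) matched 13327. No coordinates are printed, and no check of gene length or GC content was made, because an annotation of build mm9 was not used here.

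RPKM values hold no read counts, so the absolute depth is unknown. Relative depth was read from values under 0.6 RPKM, which are multiples of what 1 read of a gene is worth. Set to 1 for input 1, it was 1.39 for input 2, 1.22 for input 3, 1.39 for IP 1, 1.59 for IP 2 and 1.39 for IP 3. With these depths, 14.3% of 8684 pairs of low values lay within 1% of a ratio of whole numbers up to 4. Over 200 random offsets the median share was 7.62% and the highest 10.0%. The depths had been chosen to fit these same values, so a higher share than at random offsets was built in and does not test them.

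Values were analysed as log2(RPKM + 1) for the 12328 genes with at least 1 RPKM in 3 or more of the 6 libraries. A fold on this scale understates the change of genes with low RPKM. IP and input were compared with limma 3.58.1 (moderated linear model with a mean-variance trend) in R 4.3.3, two-sided, over all 6 libraries with no block. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the depth estimate and the plots. The limma and camera tests of IP against input, the gene lists, the naming rule and all alternatives but those said to be added were fixed before the data were examined. The tests of explanations in the closing section were written after the largest folds had been seen.

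A set of 26 gene lists was fixed from textbook markers and symbol patterns, and 22 of them had the required 5 or more members among the genes tested. Each was compared with the other genes by limma's camera test with a preset correlation of 0.01, adjusted over the 22 lists, and again with a correlation estimated per list. Mitochondrially encoded transcripts were among the lists, but no symbol in the table matched their pattern. The patterns for ribosomal proteins and respiratory chain subunits also took in kinases, assembly factors and other genes such as Cox4nb. These were kept as fixed and left out in an added alternative. The text names Adcyap1, Bdnf and Fos in every case. It also names the 8 genes with the largest folds in each direction among those past the threshold that moved the same way in all 3 pairs and had a mean of at least 5 RPKM in the higher fraction. From each list it names the 2 members past the threshold with the largest absolute fold, or the 2 with the smallest p where none passed. Other list members are given as further values, and were chosen after their values were seen. Not every gene that the rule names is reported here.

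Input and IP share the number of their warm challenge in the labels, and the samples were taken as paired on that ground. Counts of calls from the fits with and without the block had already been seen when this was decided. Deviations from the group means correlated within pairs by 0.05 for number 1, 0.61 for number 2 and 0.27 for number 3, across genes. IP 1 and IP 3 both correlated best with input 3, and IP 2 with input 2. The fit with the warm challenge as a block called 656 genes (164 higher and 492 lower in IP), against 516 without it. The main fit nonetheless had no block, so values given without mention of the block ignore the pairing. Single libraries rather than pairs were left out. Without the block, differences between warm challenges stay in the error of a gene. The SE of Adcyap1 was 0.56 without and 0.22 with the block, while that of Ermn was 0.34 and 0.36.

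The alternatives were the block, median scaling, quantile normalization, no filter, a filter of 5 RPKM, pseudocounts of 0.1 and 5, limma without the trend, a 2-fold minimum, an adjusted p under 0.01, and each library left out in turn. The gene and list tests were checked on simulated data of the same 12328 genes, with 200 genes changed in each of 20 draws. They recovered 9.15% of genes changed 2-fold and 63.7% of those changed 4-fold, and 3.77% of calls were false. Shifted lists were called in 20 of 20 draws and unshifted lists in 0 of 400 tests. The simulated noise was independent between genes, while the correlation estimated within lists of these data reached 0.73 (ribosomal proteins). The simulation therefore does not show how often lists of correlated genes are called falsely. It also held no difference between warm challenges and fewer changed genes than the 516 called in the real comparison. Recovery under this adjustment depends on the share of changed genes, so the rates may differ here. The labels do not tie libraries to single animals, so p-values measure the spread between these samples, which may be partly technical. No pair of libraries shared more than 23 identical values, and each was counted as a separate sample. A group kept at another temperature is not analysed here, so the comparison is between RNA fractions of warm-challenged mice.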

Results

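The data were RPKM values of 13724 gene entries in 3 inputs (total RNA) and 3 phospho-S6 immunoprecipitates (IP) from the anterior hypothalamus of warm-challenged mice. Summed RPKM lay between 374708 and 496125 per library. Relative depth, an untested estimate from low values, lay between 1 and 1.59, while the absolute depth is unknown. Spearman correlations across genes were 0.952 to 0.980 among inputs, 0.915 to 0.955 among IP libraries and 0.902 to 0.941 between the fractions. The first principal component held 43.2% of the variance and parted inputs (-31.5 to -25.2) from IP libraries (10.3 to 41.3). The next one, with 26.0%, set IP 1 (-49.0) apart from the other libraries (-10.0 to 19.9).

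The comparison of IP with input addressed which transcripts are enriched in the RNA bound to phosphorylated S6 in warm-challenged mice. Without a group at another temperature, it does not tie an enrichment to warmth. Activity-induced transcription factors and several neuropeptides were higher in IP, and myelin genes were lower. Fosb, a subunit of the AP-1 transcription factor induced by neuronal firing, stood at 3.54 ± 1.08 RPKM in input and 75.1 ± 13.1 RPKM in IP (SD, n = 3 each), a log2 fold of 4.08 (SE 0.24, adjusted p = 0.000308). Adcyap1, which encodes the neuropeptide PACAP, stood at 11.1 ± 8.24 RPKM in input and 107 ± 75.5 RPKM in IP, a log2 fold of 3.18 (SE 0.56, adjusted p = 0.0257). Bdnf, a neurotrophin, stood at 5.11 ± 1.98 and 47.0 ± 29.3 RPKM, a log2 fold of 2.86 (SE 0.39, adjusted p = 0.0122). The study chose Adcyap1 and Bdnf as markers on these same samples, so both are no independent evidence here.

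In all, 110 genes were higher and 406 lower in IP at an adjusted p under 0.05 (limma), or 516 of 12328, and 3005 had an unadjusted p under 0.05. The median log2 fold of all genes was -0.18, and scaling each library to a common median gave 114 higher and 103 lower, while quantile normalization gave 129 and 124. The share of lower calls was thus 78.7% without and 47.5% with median scaling. The count was 35, 21 and 39 without input 1, 2 and 3, and 1693, 67 and 94 without IP 1, 2 and 3. Without IP 1, 443 genes were higher and 1250 lower.

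The 8 largest folds higher in IP belonged to Fosb, Rrad, Hbb-b1, Adcyap1, Fosl2, LOC100503605, Hba-a1 and Hba-a2. Rrad, a small GTPase that acts on calcium channels, had a log2 fold of 3.29 (SE 0.47, adjusted p = 0.0131). Fosl2, another AP-1 subunit, had 3.01 (SE 0.25, adjusted p = 0.00131), and LOC100503605 had 2.98 (SE 0.65, adjusted p = 0.0417, and 0.0520 with a pseudocount of 0.1). The 8 largest folds lower in IP belonged to Mtrnr2l, Ermn, Mal, Cdr1, Gm4076, LOC100502983, Pwwp2a and Efhd1. Mtrnr2l, which RefSeq lists as an older symbol of Gm20594, stood at 13724 ± 3151 RPKM in input and 625 ± 449 RPKM in IP, a log2 fold of -4.90 (adjusted p = 0.0175). It took 2.35% to 3.63% of the summed RPKM of each input. Cdr1 had a log2 fold of -3.31 (SE 0.24, adjusted p = 0.00102), Gm4076 -3.30 (adjusted p = 0.0107) and LOC100502983 -3.00 (adjusted p = 0.0175). Pwwp2a had -2.88 (adjusted p = 0.0339) and was not past the threshold after median scaling (adjusted p = 0.0530), and Efhd1 had -2.84 (adjusted p = 0.00607). Of these 16 genes, 7 kept their call whichever library was left out, namely Fosb, Fosl2, Ermn, Mal, Cdr1, Gm4076 and Efhd1. Another 9 lost it in at least 1 omission, and LOC100503605, Pwwp2a, Hbb-b1 and Hba-a1 kept it in that of IP 1 alone. The call of Rrad ended without input 2 or input 3, that of Mtrnr2l without any 1 input, and that of LOC100502983 without input 3, IP 2 or IP 3. Most calls of any gene ended in such omissions, which leave fewer samples. Of the calls tested, 21 of 486 held without input 2, 37 of 486 without input 3 and 63 of 510 without IP 2. A lost call is thus not particular to the genes named. The highest adjusted p over the 6 omissions was 0.10 for Adcyap1 (calls ended without input 2, input 3 or IP 2) and 0.0608 for Bdnf (without input 2 or input 3). With the warm challenge as a block, both genes had an adjusted p of 0.00676 over the 6 libraries.

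**Figure D1:**
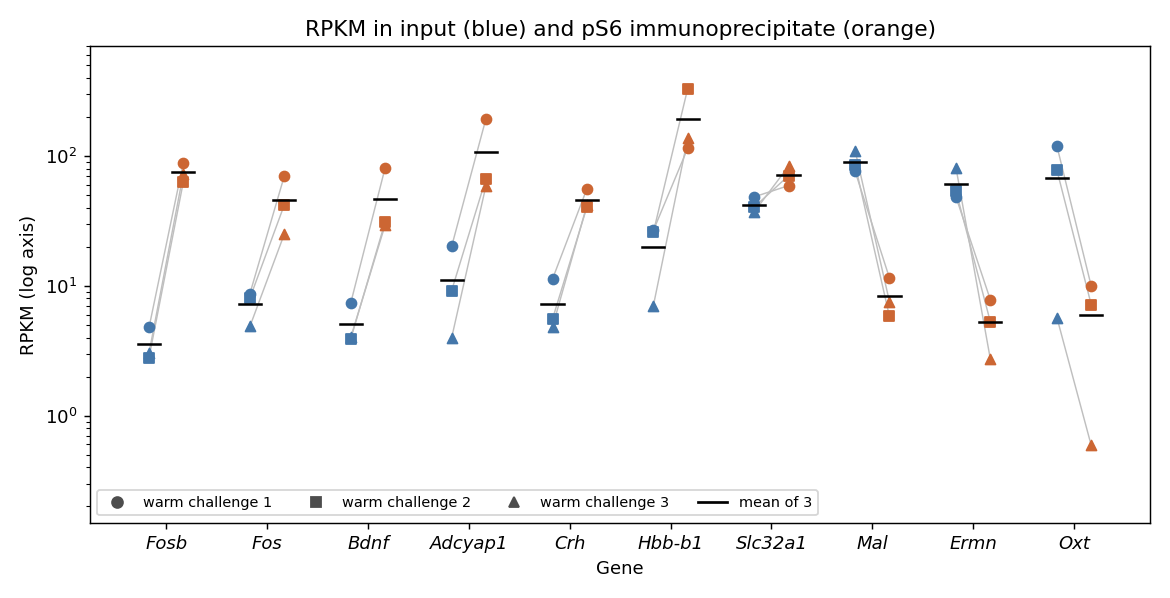
RPKM (log axis) of 10 genes in each of the 6 libraries, with inputs in blue, IP libraries in orange, marker shape for the warm challenge, grey lines joining pairs and black bars for the means of 3. Fosb rose from a mean of 3.54 to 75.1 RPKM, and Mal fell from 90.6 to 8.30 RPKM.

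Activity-regulated (immediate early) genes were higher in IP as a group. Of 33 members tested, 17 were higher, 0 lower and 16 did not pass, with a median log2 fold of 1.57. Adjusted over the list alone, 25 were higher. All 33 had a positive fold. Fos, the classical marker of recent neuronal activity, stood at 7.21 ± 2.05 RPKM in input and 45.5 ± 22.6 RPKM in IP, a log2 fold of 2.42 (SE 0.36, adjusted p = 0.0161), and its call ended without any 1 of inputs 1, 2 and 3 or IP 2. The transcription factors Junb (log2 fold 2.07, adjusted p = 0.00496), Egr4 (2.06, adjusted p = 0.0264) and Nr4a3 (2.09, adjusted p = 0.0188) were higher, as was Crem, a cAMP-responsive regulator (2.11, adjusted p = 0.0155). Junb kept its call in all 6 omissions, while those of Egr4, Nr4a3 and Crem ended in 4, 3 and 3 of them, among them inputs 2 and 3. Arc, a synaptic immediate early gene, had a log2 fold of 1.57 (adjusted p = 0.0630), and 0.0225 with the warm challenge as a block. The list stood above the other genes by camera (adjusted p = 2.1e-31), and also with an estimated correlation (adjusted p = 0.0124). With the block and an estimated correlation together, an alternative added after seeing the data, this call was lost (adjusted p = 0.209). The members called were 5, 3 and 3 without input 1, 2 and 3, and 19, 9 and 9 without IP 1, 2 and 3.

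Of 32 neuropeptides tested, 5 were higher in IP, 0 lower and 27 did not pass, and adjusted over the list alone 6 were higher and 3 lower, with Nts, Gnrh1, Ucn3 (log2 fold -1.06, adjusted p = 0.0620 over all genes) and Tac2 (-1.34, adjusted p = 0.1006) added. The 5 were Adcyap1, Bdnf, Crh, Vgf and Nms, of which Bdnf and Vgf are also in the activity list. Crh, corticotropin-releasing hormone, stood at 7.23 ± 3.54 RPKM in input and 45.9 ± 8.58 RPKM in IP (log2 fold 2.58, adjusted p = 0.00664). Vgf had a log2 fold of 2.37 (adjusted p = 0.0295), and Nms, neuromedin S, 2.02 (adjusted p = 0.0266). Crh kept its call in all 6 omissions, and Vgf and Nms in 2 of them, the omission of IP 1 being 1 of these. With the warm challenge as a block, 8 members were higher and 2 lower. Nts (log2 fold 1.44, blocked adjusted p = 0.0467), Pnoc (1.23, blocked adjusted p = 0.0254) and Scg2 (1.36, blocked adjusted p = 0.0467) joined the higher ones. The lower ones in the blocked fit were Oxt, oxytocin (log2 fold -2.93, adjusted p = 0.125 without and 0.0125 with the block), and Gnrh1 (-2.10, adjusted p = 0.0698 without and 0.0304 with the block). By camera the list stood above the other genes (adjusted p = 0.000166), with a median log2 fold of 0.32 (0.24 without IP 1 to 0.60 without input 1), and this call was lost at an adjusted p = 0.536 with an estimated correlation. Members higher in IP were 3, 1 and 1 without input 1, 2 and 3, and 6, 3 and 4 without IP 1, 2 and 3.

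Among receptors for peptides, steroids and prostaglandins, 1 of 33 was higher and 0 lower, against 1 higher and 2 lower when adjusted over the list alone. Galr1, a galanin receptor, stood at 1.28 ± 0.113 RPKM in input and 9.07 ± 7.03 RPKM in IP (log2 fold 1.93, adjusted p = 0.0361), a call held in 1 of the 6 omissions, that of IP 1, and lost with a pseudocount of 5 (adjusted p = 0.0619). Lepr, the leptin receptor, had a log2 fold of -1.04 (adjusted p = 0.0562), and 0.0473 with the warm challenge as a block. Lepr and the neuropeptide Y receptor gene Npy1r (log2 fold -1.05, adjusted p = 0.0648) were the lower ones over the list alone. Camera placed this list above the other genes (adjusted p = 0.0306, median log2 fold 0.04), but with an estimated correlation the adjusted p was 0.536. This call also ended without input 2 (adjusted p = 0.247, median -0.07), without IP 1 (adjusted p = 0.164) and with a filter of 5 RPKM (adjusted p = 0.292), while without IP 1 Crhr1 and Galr1 were higher and Lepr and Npy1r lower.

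Neuronal identity markers showed no member past the threshold over the 6 libraries. This held for 21 pan-neuronal genes, 11 GABAergic markers, 7 glutamatergic markers, 9 monoaminergic and cholinergic markers and 19 transcription factors of hypothalamic neurons, and also when adjusted over the list alone. In the simulated data only 9.15% of 2-fold changes were recovered, so the lack of calls does not show that these markers were unchanged. Slc32a1, the vesicular GABA transporter, had a log2 fold of 0.74 (adjusted p = 0.0975) and Gad1, a GABA-synthesizing enzyme, 0.89 (adjusted p = 0.123). Grin2b had 0.56 (adjusted p = 0.254), Slc17a8 -0.45 (adjusted p = 0.316), Nos1 0.49 (adjusted p = 0.337) and Slc18a2 -0.64 (adjusted p = 0.227). Zic1 had 0.72 (adjusted p = 0.106) and Fezf1 0.86 (adjusted p = 0.108), and the neurofilament genes Nefl 0.82 (adjusted p = 0.0976) and Nefh 0.78 (adjusted p = 0.0986). As a list the pan-neuronal genes stood above the other genes (camera, adjusted p = 0.0185, median log2 fold 0.07, from 0.05 without input 2 to 0.16 without IP 1), with an adjusted p = 0.288 with an estimated correlation. The GABAergic (adjusted p = 0.0738, median 0.16), glutamatergic (0.223, median 0.04), monoaminergic and cholinergic (0.308, median -0.09) and transcription factor lists (0.187, median -0.20) did not pass. The monoaminergic median turned positive after both scalings (0.08 each), and the transcription factor median after quantile normalization (0.07). Median scaling adds the same amount to the fold of every gene, so the turn it gave is not particular to the monoaminergic list. Single omissions also turned these medians, the monoaminergic one without input 3 (0.08), IP 1 (0.17) or IP 3 (0.05) and the transcription factor one without input 3 (0.03) or IP 1 (0.01). The glutamatergic median was -0.01 without input 2, -0.03 without IP 1 and -0.01 without IP 3. The pan-neuronal call ended after quantile normalization (adjusted p = 0.391). Without IP 1, Nefh, Nefm, Slc32a1, Six3 and Zic1 were higher and Slc18a2 lower, and camera placed the GABAergic (adjusted p = 0.0481) and transcription factor lists (adjusted p = 0.0435) above the other genes. With median scaling added to that omission, both missed the threshold (adjusted p = 0.0536 and 0.0608), and over the 6 libraries with an estimated correlation the adjusted p was 0.536 and 0.598.

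Ion channel and receptor subunit lists held few single calls. Of 60 potassium channel subunits, 2 were higher and 1 lower, and the same numbers were called when adjusted over the list alone. Kcng4 had a log2 fold of 1.30 (adjusted p = 0.0192), Kcnj3 1.18 (adjusted p = 0.0341) and Kcnj10, a channel of glial cells, -1.06 (adjusted p = 0.0421). Kcnj10 did not pass after median scaling (adjusted p = 0.0782) or quantile normalization (adjusted p = 0.0738), and Kcng4 in none of the 3 omissions in which it was tested, those of the inputs. With the block 4 potassium channel subunits were higher, Kcnab3 (log2 fold 1.38, blocked adjusted p = 0.0412) and Kcnk9 (1.28, blocked adjusted p = 0.0417) among them, and 1 lower, and without IP 1 there were 9 higher and 2 lower. Of 23 glutamate receptor subunits, Grik5 was higher (log2 fold 1.37, adjusted p = 0.0465), and 2 were higher over the list alone. The other was Grin1, an NMDA receptor subunit, with 1.09 (adjusted p = 0.0540, and 0.0372 with the block). Grik5, Kcnj3 and Kcnj10 kept their calls in 1 of the 6 omissions, that of IP 1, and Grik5 also lost it with no filter, a pseudocount of 0.1 or 5, or no trend (adjusted p = 0.05004 to 0.0524). None of 31 sodium and calcium channel subunits passed by limma, and Cacna1a had 0.73 (adjusted p = 0.112) and Cacng2 0.92 (adjusted p = 0.114). No member passed among 15 GABA receptor subunits (Gabra2 0.51, adjusted p = 0.278). The same held for 12 temperature-gated and pacemaker channels (Hcn4 0.51, adjusted p = 0.266, and Hcn3 -0.34, adjusted p = 0.386). In these 3 lists 0 members passed over the list alone too. Without IP 1, however, 3 sodium and calcium channel subunits were higher (Cacng2, Cacng7 and Cacng8) and 3 GABA receptor subunits lower, Gabrb1 and Gabrg1 among them. Camera placed potassium channels (adjusted p = 5.9e-06), sodium and calcium channels (adjusted p = 0.0104) and glutamate receptors (adjusted p = 0.0306) above the other genes. With an estimated correlation the adjusted p was 0.536, 0.598 and 0.598 in that order. The call of sodium and calcium channels ended without input 2 (adjusted p = 0.137) or IP 1 (adjusted p = 0.0575) and with a filter of 5 RPKM (adjusted p = 0.0929), and that of glutamate receptors without input 2 (adjusted p = 0.247), IP 1 (adjusted p = 0.125) or IP 3 (adjusted p = 0.108) and with that filter (adjusted p = 0.173). GABA receptors were called above the other genes without IP 2 (adjusted p = 0.0356). Without IP 1 their camera direction turned (adjusted p = 0.916), and over the 6 libraries with an estimated correlation the adjusted p was 0.648. The glutamate receptor median was -0.02 although its mean was 0.12, and the median was 0.16 after median scaling. Camera's adjusted p was 0.223 for GABA receptors and 0.187 for the temperature-gated list, whose median of -0.03 became 0.14 after median scaling. Leaving out 1 library moved the median from -0.12 (input 2) to 0.28 (IP 2) for GABA receptors, from -0.12 (IP 3) to 0.19 (IP 2) for glutamate receptors and from -0.07 (input 2) to 0.09 (IP 2) for the temperature-gated list. For sodium and calcium channels the median was 0.12 over the 6 libraries and -0.01 without IP 1, and for potassium channels it was 0.21 and 0.05 without IP 3.

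Oligodendrocyte genes were lower in IP as a group. Of 19 members tested, 0 were higher, 14 lower and 5 did not pass, and 16 were lower adjusted over the list alone, with a median log2 fold of -1.69. Ermn, a myelin cytoskeletal gene, stood at 60.9 ± 17.5 RPKM in input and 5.29 ± 2.55 RPKM in IP (log2 fold -3.35, SE 0.34, adjusted p = 0.00385). Mal, a myelin proteolipid gene, stood at 90.6 ± 17.6 and 8.30 ± 2.91 RPKM (log2 fold -3.33, SE 0.27, adjusted p = 0.00131). The abundant myelin gene Mbp (log2 fold -1.18, adjusted p = 0.0422) was lower too, although it did not pass after median scaling (adjusted p = 0.0813). Ermn and Mal kept their calls in all 6 omissions, and Mbp in 1. Cnp had a log2 fold of 0.04 (adjusted p = 0.966) and Sox10 -0.23 (adjusted p = 0.780). The list stood below the other genes by camera (adjusted p = 2.0e-13), and also with an estimated correlation (adjusted p = 0.0124). It did not pass in the added alternative of block and estimated correlation together (adjusted p = 0.209). After median scaling 11 members were lower (median -1.52), and after quantile normalization 12 (median -1.56). The lower members numbered 6, 5 and 7 without input 1, 2 and 3, and 14, 8 and 10 without IP 1, 2 and 3.

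Astrocyte markers had a median log2 fold of -0.61 (-0.88 without IP 1 to -0.34 without IP 2), with 0 of 18 past the threshold by limma and 4 lower adjusted over the list alone, Aqp4, Gfap, Glul and Ntsr2. Glul, glutamine synthetase, had -1.31 (adjusted p = 0.0518) and Ntsr2 -1.23 (adjusted p = 0.0517). With the warm challenge as a block, 3 were lower, namely Glul (adjusted p = 0.0364, and 0.0464 without the trend and the block), Ntsr2 (adjusted p = 0.0352) and the water channel gene Aqp4 (adjusted p = 0.0400). Without IP 1, 7 were lower. The list's camera adjusted p was 0.0518, 0.0159 with the block and 0.598 with an estimated correlation. It was 0.0337 after median scaling, 0.0403 after quantile normalization, 0.00264 without input 2 and 0.00878 without IP 1. Oligodendrocyte precursor markers went both ways, with 1 of 8 higher and 1 lower over all genes and over the list alone (camera adjusted p = 0.590). Gpr17 was higher (log2 fold 1.36, adjusted p = 0.0433) and the transcription factor Olig1 lower (-1.48, adjusted p = 0.0314), but Olig1 did not pass after median scaling (adjusted p = 0.0565). The call of Gpr17 held in 1 of the 6 omissions, that of IP 1, and ended with no filter (adjusted p = 0.0506), and the call of Olig1 in 2, those of IP 1 and IP 2. Their list median was -0.25 (-0.31 without input 2 to -0.11 without input 3), and 0.04 after quantile normalization. None of 7 microglia markers passed, over all genes or over the list alone (Ctss -0.84, adjusted p = 0.205, and Aif1 -0.59, adjusted p = 0.296), and the list median was -0.49 (camera adjusted p = 0.399), with -0.09 without input 1, -0.31 without IP 1 and -0.27 without IP 2. Rgs5, a pericyte marker, was the 1 endothelial and mural gene of 5 that was lower (log2 fold -1.32, adjusted p = 0.0305), against 2 over the list alone, where Myl9 (-1.04, adjusted p = 0.0703) joined it. Rgs5 did not pass after quantile normalization (adjusted p = 0.0608), nor without any 1 of the inputs or IP 2. Ccdc153, a gene of ciliated ependymal cells, was the 1 of 9 ependymal and choroid plexus genes that was lower (log2 fold -1.70, adjusted p = 0.0465), against 3 over the list alone, where Dynlrb2 (-1.64, adjusted p = 0.107) and Foxj1 (-0.88, adjusted p = 0.115) joined it. Ccdc153 did not pass after median scaling (adjusted p = 0.0845) or quantile normalization (adjusted p = 0.0873), nor with no filter, a pseudocount of 0.1 or no trend (adjusted p = 0.0512 to 0.0572), and held in 1 of the 6 omissions, that of IP 1. Camera's adjusted p was 0.187 for endothelial and mural genes and 0.424 for ependymal genes. The meningeal list had too few members for a list test, with Igf2 at -1.19 (adjusted p = 0.0934) and Dcn at -0.34 (adjusted p = 0.550).

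**Figure D2:**
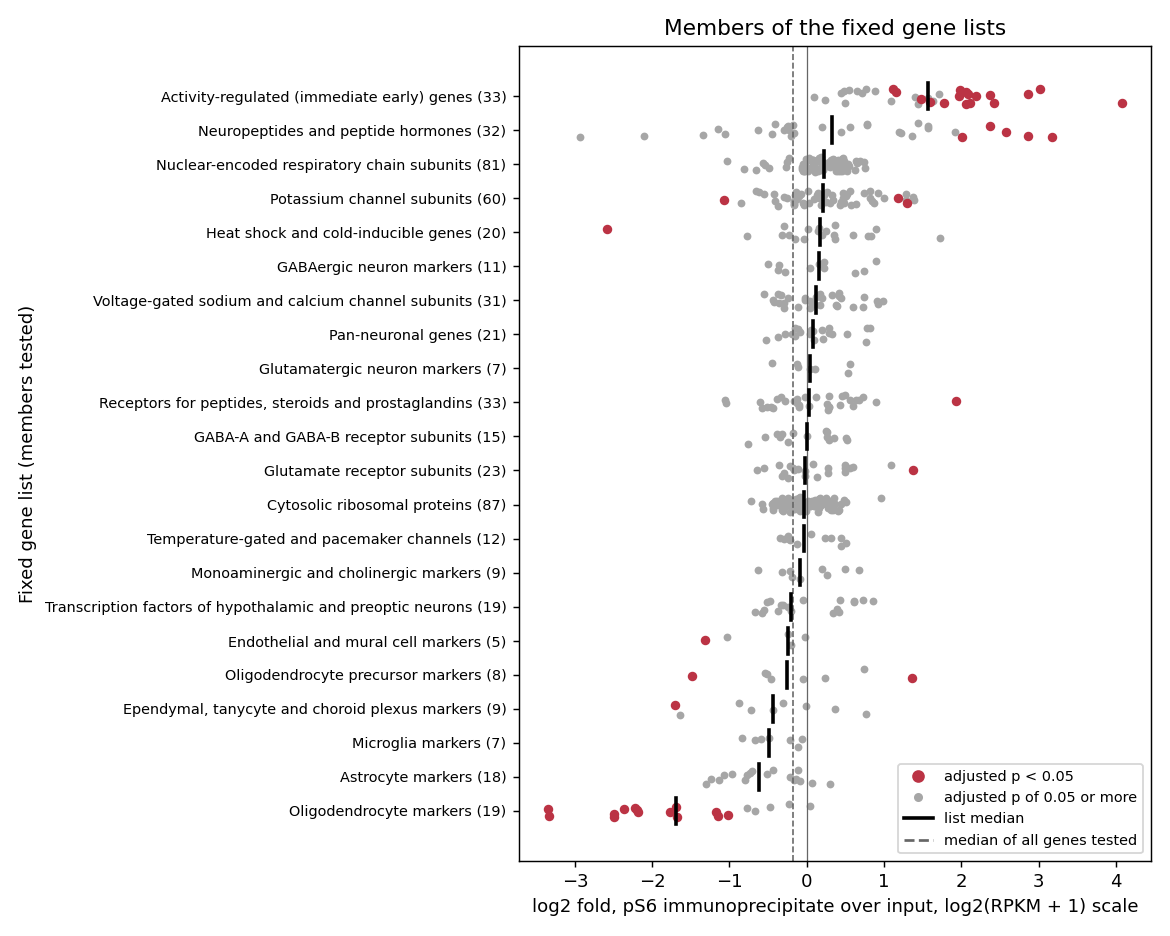
Log2 fold of IP over input on the log2(RPKM + 1) scale (horizontal axis) for each tested member of 22 gene lists (vertical axis), with points in red at an adjusted p under 0.05 and in grey otherwise, black ticks for list medians and a dashed line for the median of all genes (-0.18). The activity list has the highest median (1.57) and the oligodendrocyte list the lowest (-1.69).

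Hemoglobin transcripts were higher in IP. Hbb-b1 stood at 19.9 ± 11.1 RPKM in input and 194 ± 119 RPKM in IP (log2 fold 3.26, SE 0.53, adjusted p = 0.0192). Hba-a1 had a log2 fold of 2.90 (adjusted p = 0.0240) and Hba-a2 2.90 (adjusted p = 0.0162), but these alpha-globin genes are near-identical and the reads of each are uncertain. These were the 3 members of the red blood cell list tested, and all 3 were higher over the list alone as well. LOC100503605 was not matched to the list by its symbol, and what it encodes was not checked. Its log2 differences in pairs 1, 2 and 3 were 1.75, 3.24 and 3.95, near those of Hba-a1 (1.79, 3.32 and 3.60). Hbb-b1 and Hba-a1 kept their calls in 1 of the 6 omissions, that of IP 1 (highest adjusted p 0.0580 and 0.0698), and the call of Hba-a2 ended without input 2 or input 3 (highest adjusted p 0.0608).

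Heat shock and cold-inducible genes included 0 higher and 1 lower of 20, and 1 higher and 1 lower over the list alone. Cryab, a small heat shock protein gene also expressed in glia, stood at 220 ± 41.0 RPKM in input and 36.5 ± 11.3 RPKM in IP (log2 fold -2.59, adjusted p = 0.00496), and it kept its call in all 6 omissions. Hspa1a, the inducible heat shock protein 70 gene, had 1.73 (adjusted p = 0.0624), and 0.0361 with the block. Camera placed the list above the other genes (adjusted p = 0.0306, median log2 fold 0.18, from 0.10 without IP 1 to 0.29 without IP 3), with an adjusted p = 0.598 with an estimated correlation. This call ended after median scaling (adjusted p = 0.0562), after quantile normalization (adjusted p = 0.391), and without input 3 (adjusted p = 0.10), IP 1 (adjusted p = 0.135) or IP 2 (adjusted p = 0.0784), and with a filter of 5 RPKM (adjusted p = 0.104). Snhg11, the 1 noncoding RNA tested of its list, had a log2 fold of -2.68 (adjusted p = 0.0575), and 0.0444 with the block.

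Ribosomal protein and respiratory chain genes held no member past the threshold by limma over the 6 libraries, over all genes or over the list alone. The 87 ribosomal members had a median log2 fold of -0.03 and a mean of -0.02, yet camera placed them above the other genes (adjusted p = 0.0342), with an adjusted p = 0.705 with an estimated correlation. Without 7 kinases that matched the pattern, an alternative added after seeing the data, the adjusted p was 0.0541. The median was 0.14 after median scaling, where the adjusted p was 0.156, and -0.07 after quantile normalization, where it was 0.562. With a filter of 5 RPKM the adjusted p was 0.0929. Without IP 2 the median was -0.30 (adjusted p = 0.835). Without input 3 it was -0.45, and camera placed the list below the other genes (adjusted p = 0.0452). In the other 4 omissions the median lay between 0.02 and 0.20, and camera placed the list above the other genes (adjusted p 0.000180 to 0.00682). Rps6ka3, an S6 kinase matched by the pattern, had 0.97 (adjusted p = 0.157), and 0.0439 with the block, and Rpl7l1 had -0.57 (adjusted p = 0.224). The 81 respiratory chain members had a median of 0.22 (camera adjusted p = 1.0e-04), with an adjusted p = 0.598 with an estimated correlation. The respiratory chain median was -0.06 without input 3 (adjusted p = 0.196), -0.09 without IP 2 (adjusted p = 0.196) and 0.63 without IP 1, and after quantile normalization the adjusted p was 0.0755. Without IP 1, Ndufab1 was higher and Cox4nb lower, but Cox4nb was matched by its symbol alone and is left out of the added alternative. Over the 6 libraries Cox4nb had -0.81 (adjusted p = 0.0575) and Ndufaf4, an assembly factor, -0.66 (adjusted p = 0.174). Without 7 matches of these kinds, 74 members were left, with a median of 0.28. Their camera adjusted p was 1.6e-05, and 0.577 with an estimated correlation. The median log2 difference of input 3 from the other inputs was -1.31 for ribosomal and -1.11 for respiratory chain genes, and that of IP 1 from the other IP libraries was -0.63 and -1.08.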

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

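Settings that combine choices were added after seeing the data, as was the list alternative without kinases and assembly factors. Of the 516 calls, all that were tested kept their sign in every setting, omissions included. These calls had been selected on the same libraries, so a turn of sign was unlikely from the start and the kept sign is no independent evidence. The gene count stayed within 1.5 times under the replicate block (656), no filter (459), a filter of 5 RPKM (421), pseudocounts of 0.1 (442) and 5 (515), no trend (453), a 2-fold minimum (430), and block with median scaling (377). It was 217 after median scaling, 253 after quantile normalization, 28 at an adjusted p under 0.01, and 1140 without IP 1 after median scaling. Lower calls were 103 after median scaling, 124 after quantile normalization and 167 with block and median scaling. Higher calls were 210 with block and median scaling and 579 without IP 1 after median scaling. Leaving out 1 library gave 21 to 1693 genes, 4 to 443 higher and 17 to 1250 lower. The extremes were without input 2 and without IP 1, and the omission of any library but IP 1 lowered the count while leaving fewer samples. Of 516 calls, 210 remained after median scaling and 222 after quantile normalization, and 509 of 510 tested without IP 1. In the other omissions, between 21 of 486 tested (without input 2) and 90 of 510 tested (without IP 3) remained.

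Of 22 lists, 11 were called, 10 after median scaling, 8 after quantile normalization and 12 with the replicate block. With an estimated correlation 2 were called, and 0 with block and estimated correlation together. A filter of 5 RPKM left fewer genes and only 19 lists to test, of which 6 were called. It ended the receptor, heat shock, ribosomal, glutamate receptor and sodium and calcium channel calls. Both scalings ended the heat shock and ribosomal calls and added the astrocyte list, and quantile normalization also ended the pan-neuronal and respiratory chain calls. Beyond the calls given with each gene and list, the block changed no call of a named gene or list. The difference between a list's mean log2 fold and that of all other genes turned negative for ribosomal proteins after quantile normalization (-0.0525), without input 3 (-0.23, range over omissions to 0.34) and without IP 2 (-0.0674, where the camera direction did not turn). It turned negative for GABA receptors without IP 1 (-0.0324 with or without median scaling, range to 0.323). For microglia it stayed between -0.395 and -0.0185, the last without input 1, where the camera direction turned. Dcn turned to 0.0428 without IP 1 after median scaling. The causes were not tested. Absolute depth is unknown, so counting error of low genes cannot be given.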

Other observations

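Among the tests reported here, the Oxt test and the intervals of differences between list medians were chosen only after their values were seen, and the globin and oligodendrocyte tests after the largest folds were seen but before the values they measure. The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 516 genes, the highest other split gave 0, and 1 split of 10 reached the real count. For gene lists the real split gave 11, the highest other split 13, and 2 of the 10 splits gave as many. The split with 13 lists set input 1, IP 1 and IP 3 against the rest. Of the 4 splits that part all 3 pairs, the real one apart, the others gave 0 genes each and 7, 3 and 5 lists.

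Hemoglobin transcripts were higher in IP by log2 folds of 2.90 to 3.26 (Hba-a2 and Hbb-b1). Red blood cell RNA carried into the IP may account for this, and Alas2, an erythroid gene, had a log2 fold of 0.53 (95% interval -0.02 to 1.09) without the filter. Alas2 met the bound set beforehand against this, but it stood at only 0.385 to 0.508 RPKM in input and 0.410 to 1.83 RPKM in IP, where the added pseudocount of 1 pulls a fold toward 0, so the bound was wrong and decides nothing. For RNA of white blood cells, the median log2 fold of Coro1a, Fcer1g, Lyz2 and Tyrobp was -0.12 (members -0.67 to 0.75). This met its bound too, which was wrong because microglia express the same genes and their baseline can hide a small share, so both explanations stay open, as does hemoglobin expression in neurons, which was not tested.

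Oligodendrocyte genes were lower in IP with a median log2 fold of -1.69 (95% bootstrap interval over members -2.22 to -1.02). The median of all genes was -0.18, and the list median was -1.52 after median scaling and -1.56 after quantile normalization. Median scaling adds the same amount to every fold, so its result follows from the medians and is no separate test. The values argue against scaling between libraries as the whole cause, if the median gene is taken as alike in both fractions. For a uniform loss of all non-neuronal RNA, the microglia and astrocyte medians lay above the oligodendrocyte median by 1.21 (95% interval 0.48 to 2.08) and 1.08 (0.31 to 1.89). Both intervals reach below the difference of 1 set as the bound beforehand. The microglia interval lay above 0 in all 6 omissions of a library (difference 0.98 without input 3). Microglia markers were low, however, as Ctss (2.93 RPKM in input, 1.14 in IP) and Aif1 (1.55 and 0.635). The added pseudocount of 1 pulls such folds toward 0 in every omission, so the microglia difference decides nothing. The astrocyte difference was 0.96 (0.08 to 1.68) without input 2 and 0.84 (-0.12 to 1.78) without IP 1. These intervals resample list members with the libraries held fixed, so they do not measure the spread between samples. They also treat members as independent, while the correlation estimated within the astrocyte list was 0.52. For the listed markers, the astrocyte difference argues against a uniform loss over the 6 libraries, but not without IP 1. A loss that differs between cell types, or little phosphorylated S6 in oligodendrocytes, may remain as a hypothesis that these data do not test.

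Oxytocin transcripts (Oxt) stood at 120, 78.0 and 5.71 RPKM in inputs 1, 2 and 3, and the ratio of input to IP was 12, 10.9 and 9.64, while without the block Oxt had an adjusted p of 0.125 by limma. The SD of the 3 log2 ratios was 0.0663 of the SD of the log2 input values (0.158 against 2.38). For Gnrh1 the ratio was 8.13, 2.34 and 5.22, with an SD of the log2 ratios of 0.912 against 0.914 for the inputs, and for Avp, with IP values near the floor in IP 1 and IP 3, the SDs were 2.55 and 2.34. For Oxt the ratio was alike in all 3 pairs while the inputs differed far more, but the third ratio rests on 0.592 RPKM in IP 3. The test decides nothing on a difference in dissection between warm challenges, as its rule was written after the ratios were seen. If the number marks shared tissue, such a difference would also cancel in the ratio. For Gnrh1 and Avp the values do not exclude a difference in dissection either. A low S6 phosphorylation of oxytocin neurons in warmth stays open and was not tested.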
